A study of Danio rerio with 3 samples.

How the data were processed

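RNA-seq was analysed from 3 libraries of zebrafish embryos (Danio rerio, Tuebingen strain) collected 24 hours post fertilization: control morpholino at 3 ng, hnrnpaba morpholino at 3 ng and hnrnpaba morpholino at 6 ng, with 1 library per group and 30 embryos pooled per library. Embryos were injected at the 1-cell stage, total RNA was extracted with Trizol, and libraries were built and sequenced on a BGISEQ-500, per the labels' protocols. The labels' protocols also state that reads were mapped to a zebrafish reference genome and its genes. The aligner, the counting tool, the genome build, the annotation version, the RNA selection and the strandedness are not given in the sources used here. The labels name no sequencing batch, and the group of each library was taken from its treatment label.

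The authors deposited 1 table of FPKM values, fragments per kilobase of gene model scaled to the mapped fragments of the library, for 25961 genes with Ensembl identifiers, symbols and positions. The 2 hnrnpaba morpholino columns were matched to their libraries by name. The control column's name gives neither a morpholino nor a dose, and it was matched to the control morpholino library because that is the 1 control in the series, so each difference from the control rests on this match. In all 0 columns of values were left unused. Coordinates are those of the deposited table, whose genome build is not given. Gene symbols come from the table and, where it gave none or a clone name, from a table of gene names in which 24221 of the identifiers were found. Reads of paralogs, tandem copies and overlapping genes cannot be divided with certainty from gene-level FPKM.

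The fragment counts behind the FPKM values were recovered from the steps between low values. FPKM is a whole number of fragments divided by the length of the gene model and the library total, so genes whose length equals their span gave the totals (14589056 for the control, 17748075 at 3 ng and 13557636 at 6 ng). For each gene the shortest length that made the fragments of all 3 libraries whole, within a tolerance of at most 0.05 fragments, was taken. This gave counts for 25959 genes (99.99%), whose sums were 95.5% of each total. A shortest length can be too short by a common factor, which makes the counts too low and their intervals too wide. On simulated data, 4923 genes with known counts and lengths, 99.9% had a solution and 90.4% were recovered exactly. Recovered counts were used for depth, intervals, small RNA sums, gene lengths and simulations. The tests of explanations for small RNAs and gene length thus rest on them, but no p-value was computed from them.

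Differences between libraries are log2 ratios of FPKM with a pseudocount of 1, so the differences of genes with low values are understated. Genes with a mean over the 3 libraries of 1 FPKM or more (16429) entered the counts, and because the mean includes the morphant libraries, a gene low in the control can enter through its morphant values. Likewise a gene low in the morphant libraries can enter through its control value. A gene was counted as higher or lower at a 2-fold difference on that scale. Folds of single genes are ratios of FPKM without a pseudocount, with a 95% exact interval (Clopper-Pearson, conditional on the fragments of both libraries). The intervals cover counting error only and leave out the differences between pools of embryos. For a gene without fragments in the control, the fold is a lower bound computed against a floor of 3 fragments. With 1 library per group no test across genes was possible, and no p-value was computed.

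The 2-fold rule was tried on simulated data with the depths of the 3 ng and control libraries, with 200 genes changed by known folds in 4 sizes of 50 genes each. It called 0% of genes changed 1.5-fold, 80.0% of those changed 2.5-fold, 98.0% of those changed 4-fold and 76.0% of those at 0.25-fold, and 0.179% of 16227 unchanged genes. These draws held counting error only and no difference between pools of embryos, so the rate of false calls in these libraries is not known. Because both doses share the control, unchanged libraries were simulated 20 times around the pooled rate of each gene, with counting error alone and with an added coefficient of variation of 0.2. At 3 ng a mean of 13.5 unchanged genes were called higher and 12.3 lower with counting error alone. With the added spread the means were 85.2 and 84.3.

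There were 53 gene lists with 1873 symbols. In all 1784 symbols were matched to the table, 1590 by its own symbol, 170 by the table of gene names and 24 by a RefSeq symbol or synonym (assembly GRCz12tu), and 89 were not matched. The match of rfc1 was left out because the row it led to is described as a ribosomal protein. irf1b is given as txndc15 in the symbol column but described as interferon regulatory factor 1b, and is named irf1b. Some lists share members, so their medians are not independent of each other. Every list had at least 5 members with a mean of 1 FPKM or more. For each list the median log2 difference was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. A list was said to stand apart below the 1st or above the 99th percentile. Of the 53 lists, 14 stood apart on the low side and 12 on the high side at 3 ng, and 20 and 15 did at 6 ng.

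The gene lists and the rule for the genes named were fixed before the data were examined. The rule takes hnrnpaba, hnrnpabb and the members of the hnRNP list that are 2-fold apart at either dose. It then takes the 12 highest and 12 lowest genes among those with a mean of 5 FPKM or more, a symbol that is no clone name and a 2-fold difference in the same direction at both doses, ranked by the smaller difference (195 higher and 103 lower genes were eligible). It adds the 6 highest and 6 lowest genes between the 2 doses, the 4 members of each list with the largest mean difference, and mdm2, cdkn1a and isg15 whatever their values, because morpholinos can raise them independently of the target. A few of the genes and 1 of the lists covered by these rules are not reported here. Alternatives fixed at the same time were pseudocounts of 0.1 and 5 FPKM, no filter, a mean of 5 FPKM or more, rescaling to equal sums (TPM), rescaling by the median ratio to the control and a limit of 1.5-fold. An alternative that subtracts the median difference of genes of like length, in 20 bins, was added after seeing the data. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.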

Results

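RNA was sequenced from zebrafish embryos of the Tuebingen strain collected 24 hours post fertilization, after injection at the 1-cell stage with a standard control morpholino or with a morpholino against hnrnpaba. A morpholino is a synthetic antisense oligomer that blocks translation or splicing of the RNA it pairs with, and hnrnpaba is 1 of the zebrafish counterparts of human HNRNPAB, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family. There were 3 libraries, each from 30 pooled embryos: control morpholino at 3 ng, hnrnpaba morpholino at 3 ng and hnrnpaba morpholino at 6 ng. Each group had 1 library, so no difference has a replicate check, no p-value is given, and each comparison describes these libraries and not the conditions. The total fragments per library recovered from the FPKM values were 14589056 for the control, 17748075 at 3 ng and 13557636 at 6 ng. Of the 25961 genes, 16429 had a mean of 1 FPKM or more and entered the counts. Differences are log2 ratios of FPKM + 1, and folds are ratios of FPKM with a 95% exact interval that covers counting error only.

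The first question was how the transcripts of the target and of its paralog compared between libraries. hnrnpaba (ENSDARG00000007960, chromosome 14, 6962271 to 6968589, plus strand) stood at 442 FPKM in the control, 459 FPKM at 3 ng and 342 FPKM at 6 ng. Its transcript was thus not lower at 3 ng, with a fold of 1.04 (1.02 to 1.06) and a log2 difference of 0.053 that became -0.028 when the libraries were rescaled to equal sums, and it was lower at 6 ng, with a fold of 0.773 (0.755 to 0.793). The paralog hnrnpabb (ENSDARG00000099865, chromosome 21, 3166519 to 3175724, plus strand) stood at 242, 244 and 215 FPKM in the same order. Of the 24 measured members of the hnRNP list, hnrnpd, which encodes an AU-rich element binding protein, was the member at least 2-fold from the control on the log2 scale with its pseudocount. Its folds were 2.03 (1.91 to 2.17) at 3 ng and 2.33 (2.18 to 2.48) at 6 ng, and its log2 difference at 3 ng, 1.002, lay at the limit. Without the pseudocount ptbp2b was past 2-fold as well, at 0.492-fold the control level (0.454 to 0.533) at 6 ng. The list as a whole was lower, with medians of -0.26 at 3 ng and -0.37 at 6 ng, both below the 1st percentile of random lists of matched expression. Within it, the splicing regulators ptbp1a (50.7, 30.0 and 30.0 FPKM) and ptbp2b (43.4, 27.3 and 21.4 FPKM) were among the members farthest below the control. Whether this morpholino blocks translation or splicing is not given in the sources used here, so the transcript level does not check the labels.

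**Figure D1:**
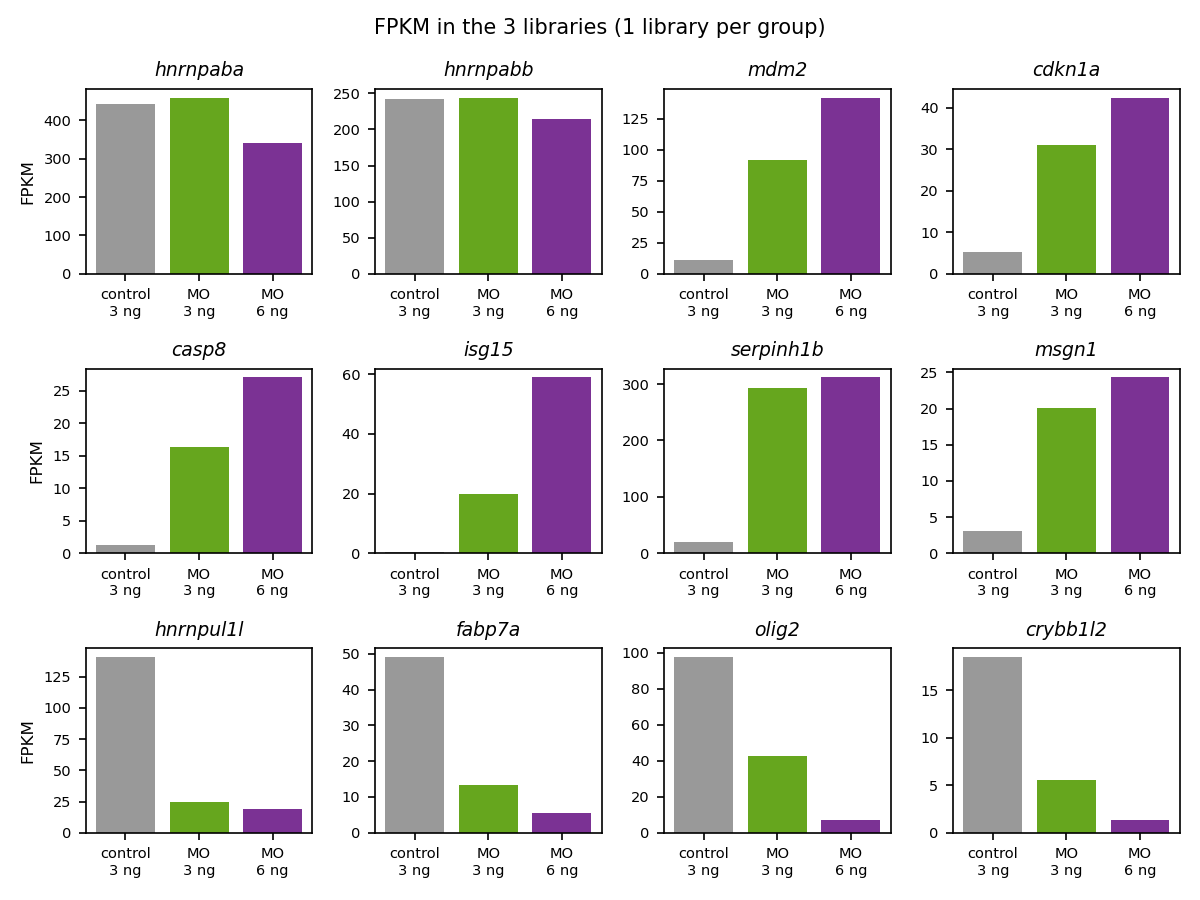
FPKM (vertical axes, each starting at 0) of 12 genes in the 3 libraries (horizontal axes), where a bar is the value of 1 library and there is no error bar because each group has 1 library. casp8 stood at 1.25 FPKM in the control and at 16.4 and 27.09 FPKM in the morphant libraries, while hnrnpul1l stood at 141, 24.5 and 19.3 FPKM.

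The embryos given 3 ng of hnrnpaba morpholino were compared with those given the same mass of control morpholino. Genes of protein folding, of presomitic mesoderm and of primitive red blood cells were higher in the hnrnpaba morphant library, and genes of DNA replication, lipid transport by the yolk, lens and neural progenitors were lower. The ubiquitin ligase gene mdm2 was 8.04-fold higher (7.17 to 9.04), and the cell cycle inhibitor cdkn1a was 5.89-fold higher (4.74 to 7.38). Other genes far above the control were rps27l (30.9 against 413 FPKM), phlda3 (5.39 against 52.5 FPKM) and the initiator caspase casp8 (1.25 against 16.4 FPKM). isg15, which encodes a ubiquitin-like modifier, stood at 0.360 FPKM in the control and 19.95 FPKM at 3 ng, a fold of 55.3 (25.2 to 152).

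Heat shock and protein folding genes had a median of 0.72 at 3 ng, with 10 of 27 measured members at least 2-fold higher and 0 lower. The collagen chaperone serpinh1b was 15.0-fold higher (14.2 to 15.9), hsp90aa1.2 was 8.06-fold higher (7.14 to 9.11) and hsp70.3 was 5.31-fold higher (4.46 to 6.36). Genes of the unfolded protein and amino acid stress response had a median of 0.45, led by the endoplasmic reticulum chaperone hspa5 (76.5 against 230 FPKM) and atf5a (3.26 against 10.5 FPKM). In the list of paraxial mesoderm and the somite clock, 12 of 28 members were at least 2-fold higher and 0 lower, with a median of 0.79. The presomitic mesoderm transcription factor msgn1 was 6.65-fold higher (5.32 to 8.41), tbx6 was 3.84-fold higher (3.38 to 4.36), and mespab, measured from few fragments in the control, was 15.6-fold higher (5.08 to 77.97). Early gastrula-stage genes had a median of 0.46, with 4 of 18 members higher (0.12 over all 31 genes of the early gastrula-stage list without the filter, inside the percentile limits), among them eve1 (2.08 against 7.26 FPKM) and foxi1 (4.58 against 12.8 FPKM).

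Embryonic globin genes had the highest list median at 3 ng, 1.35, with 6 of 9 members at least 2-fold higher. hbbe3 stood at 353 FPKM in the control and 901 FPKM at 3 ng, and hbbe1.3 stood at 60.1 and 224 FPKM. Some embryonic globin genes are near-identical tandem copies, so the division of reads between those copies is uncertain. hbbe3 and hbbe1.3 are not tandem copies of each other, as they lie on chromosomes 12 and 3. The erythroid list had a median of 0.90 with 8 of 29 members at least 2-fold higher, among them the heme synthesis genes alas2 (12.97 against 30.9 FPKM) and fech (3.83 against 8.98 FPKM). Maternal and germ line genes had a median of 1.26 with 8 of 14 members higher, among them the egg coat gene zp3b (0.702 against 6.23 FPKM). Of the 24 genes of this list in the table, 14 passed the filter. Some, such as zp3b, passed through their morphant values, so the filter favours higher members of this list at either dose. Immediate early and injury genes had a median of 0.35 with 4 of 25 members higher (mycb, fosl1a, fosab and cxcl18b). The list medians given so far for 3 ng, other than that of the hnRNP list, lay above the 99th percentile of random lists.

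On the lower side at 3 ng, 4 of 45 S phase and replication genes were at least 2-fold lower and 0 higher, with a median of -0.55. The ribonucleotide reductase subunit rrm1 stood at 0.489-fold the control level (0.470 to 0.510), cdc6, which loads the replicative helicase, at 0.440-fold (0.395 to 0.489), and ccne2 at 0.452-fold (0.408 to 0.4997). Mitosis genes had a median of -0.34 with 0 of 51 members past 2-fold. Genes of lipid transport by the yolk syncytial layer had a median of -0.79 with 7 of 24 members lower, led by apoc2 (7.82 against 1.24 FPKM), rbp4 (41.5 against 11.6 FPKM) and apoa4b.2 (47.2 against 14.5 FPKM). Endoderm, liver, gut and pancreas genes had a median of -0.40, with the fibrinogen genes fgb (9.44 against 4.04 FPKM) and fgg (6.43 against 2.21 FPKM) lower. Lens crystallins had a median of -1.12 with 12 of 17 members lower and 1, crygn1, higher, and neural progenitor genes had a median of -0.48 with 4 of 43 lower (fabp7a, sox21b, dla and sox19b). Notch pathway genes had a median of -0.44 at 3 ng, with 3 of 37 members at least 2-fold higher (her1, her7 and heyl) and 2 lower (nrarpb and dla). Hedgehog pathway genes had a median of -0.30 with 1 of 27 members higher (shhb) and 1 lower (olig2), and retina and eye field genes had -0.29 with 0 of 21 higher and 1 lower (rx2). Each of these medians on the lower side lay below the 1st percentile of random lists. Other genes far below the control at 3 ng were cyp1a, a target of the aryl hydrocarbon receptor, at 102 FPKM in the control and 15.5 FPKM at 3 ng, and hnrnpul1l, an hnRNP U-like gene outside the fixed hnRNP list, at 0.174-fold the control level (0.163 to 0.186).

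In all, 604 genes were at least 2-fold higher and 361 at least 2-fold lower at 3 ng than in the control, and the counting interval of the fold excluded 1 for 579 and 342 of them. Rescaling to equal sums gave 718 higher and 693 lower, which moved the share of higher genes from 62.6% to 50.9%. With a pseudocount of 0.1 FPKM the numbers were 1004 and 750, and with 5 FPKM they were 137 and 79.

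The library from embryos given 6 ng was compared with the same control, which had received 3 ng, so that the mass of morpholino differed as well as its target. Injury genes, also higher at 3 ng, and notochord genes were higher along with the folding and mesoderm genes, and lens, eye, neural progenitor and pigment genes were lower by more than at 3 ng. mdm2 was 12.4-fold higher than the control (11.1 to 14.0), cdkn1a 8.01-fold higher (6.45 to 10.05) and casp8 21.7-fold higher (15.7 to 30.7). Immediate early and injury genes had a median of 0.95 with 12 of 25 members higher, including the AP-1 subunit gene fosab (0.363 against 10.2 FPKM), the chemokine gene cxcl18b (0.872 against 25.4 FPKM) and the matrix metalloproteinase gene mmp9 (1.73 against 15.7 FPKM). Of 26 interferon and innate response genes, 8 had a mean of 1 FPKM or more, and their median was 1.07 with 4 higher, among them isg15 at 59.0 FPKM and mxc (0.141 against 6.27 FPKM). Some of the 8 passed the filter through their 6 ng values, so the filter favours higher members, and the interferon and innate response median over all 26 genes was 0.23. In the same list irf1b stood at 0.302 FPKM in the control and 4.23 FPKM at 6 ng.

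Paraxial mesoderm genes had a median of 1.15 at 6 ng, with 15 of 28 members at least 2-fold higher and 2 (dld and lfng) lower. Within it msgn1 was 8.04-fold higher (6.42 to 10.2), tbx6 6.29-fold higher (5.56 to 7.14), and the oscillating segmentation genes her1 and her7 were 6.68-fold (5.06 to 8.94) and 14.0-fold higher (7.12 to 31.4). Notochord and floor plate genes had a median of 0.61 with 7 of 29 members higher, among them tbxta (19.3 against 52.7 FPKM), noto (1.59 against 5.58 FPKM) and ntd5 (53.9 against 168 FPKM). Embryonic globins had a median of 1.13 and the erythroid list a median of 0.64, and heat shock genes had a median of 0.86 with 12 of 27 members higher. Early gastrula-stage genes had a median of 0.74 (0.15 without the filter, inside the percentile limits), unfolded protein response genes 0.49, hatching gland genes 0.57 and maternal and germ line genes 0.84. Each of these medians at 6 ng lay above the 99th percentile of random lists.

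Lens crystallins had the lowest list median at 6 ng, -2.08, with 15 of 17 measured members at least 2-fold lower and 0 higher. Of the 40 genes of this list in the table, 17 passed the filter. Members low in a morphant library can pass through their control values, so the filter can favour lower members of this list at either dose. The beta crystallin gene crybb1l2 stood at 0.0709-fold the control level (0.0449 to 0.107), crygn2 at 0.0865-fold (0.0551 to 0.130) and the lens water channel gene mipa at 0.0350-fold (0.0173 to 0.0635). Neural progenitor genes had a median of -1.002, with 23 of 43 members lower and 0 higher, among them fabp7a (49.1 against 5.50 FPKM), sox19a (148 against 34.5 FPKM), sox21b (19.5 against 3.56 FPKM) and the Notch ligand dla (32.2 against 5.99 FPKM). Retina and eye field genes had a median of -0.69 with 7 of 21 members lower, including rx2 (6.77 against 1.44 FPKM). Hedgehog pathway genes had a median of -0.57, with 7 of 27 members lower and 1, shhb, higher (2.43-fold, 1.86 to 3.21). The lowest member of that list was olig2, which specifies motor neuron and oligodendrocyte precursors. olig2 stood at 0.0713-fold the control level (0.0603 to 0.0837). Pan-neuronal genes had a smaller difference, with a median of -0.29 and 2 of 35 members lower, among them elavl3 (60.0 against 28.7 FPKM).

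Neural crest and pigment genes had a median of -0.31 at 6 ng with 11 of 34 members at least 2-fold lower and 1 higher. The melanin synthesis genes tyrp1b (33.6 against 3.00 FPKM) and dct (27.23 against 4.36 FPKM) and the pteridine synthesis gene gch2 (106 against 20.04 FPKM) were lower, whereas snai1b was higher (13.1 against 37.5 FPKM). S phase genes had a median of -0.77 with 16 of 45 members lower, mitosis genes -0.47 with 4 of 51 lower (nusap1, smc2, smc4 and bub1), Notch pathway genes -0.50 with 11 of 37 lower and 2 higher, and yolk lipid genes -0.56 with 9 of 24 lower. The 2 higher Notch pathway members were the segmentation genes her1 and her7, while nrarpb stood at 0.204-fold the control level (0.176 to 0.235). her1 and her7 are also in the paraxial mesoderm list, and Notch members such as dla are also in the neural progenitor list. The Notch values are thus not separate from those lists. Skeletal muscle genes had a median of -0.37 with 5 of 56 members lower and 3 higher, and they went both ways, with the fast myosin gene myhz1.1 lower (385 against 131 FPKM) and acta1a higher (335 against 829 FPKM). The medians of the lens, neural, eye, Hedgehog, pigment, cell cycle, Notch, yolk and muscle lists at 6 ng lay below the 1st percentile of random lists. Other genes far below the control at both doses were the myelin protein gene plp1a (44.2, 11.2 and 4.13 FPKM), prtgb (19.2, 4.53 and 2.499 FPKM), lrrn1 (85.1, 24.8 and 14.1 FPKM) and ndst3 (12.5, 3.35 and 1.37 FPKM).

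In all, 1032 genes were at least 2-fold higher and 745 at least 2-fold lower at 6 ng than in the control, and the counting interval excluded 1 for 1006 and 716 of them. Subtracting the median difference of genes of like length, a setting chosen after seeing the data, gave 780 higher and 905 lower and moved the share of higher genes from 58.1% to 46.3%. Rescaling by the median ratio gave 852 higher and 875 lower, a share of 49.3%. With a pseudocount of 0.1 FPKM the numbers were 1615 and 1171, and with 5 FPKM they were 313 and 215.

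**Figure D2:**
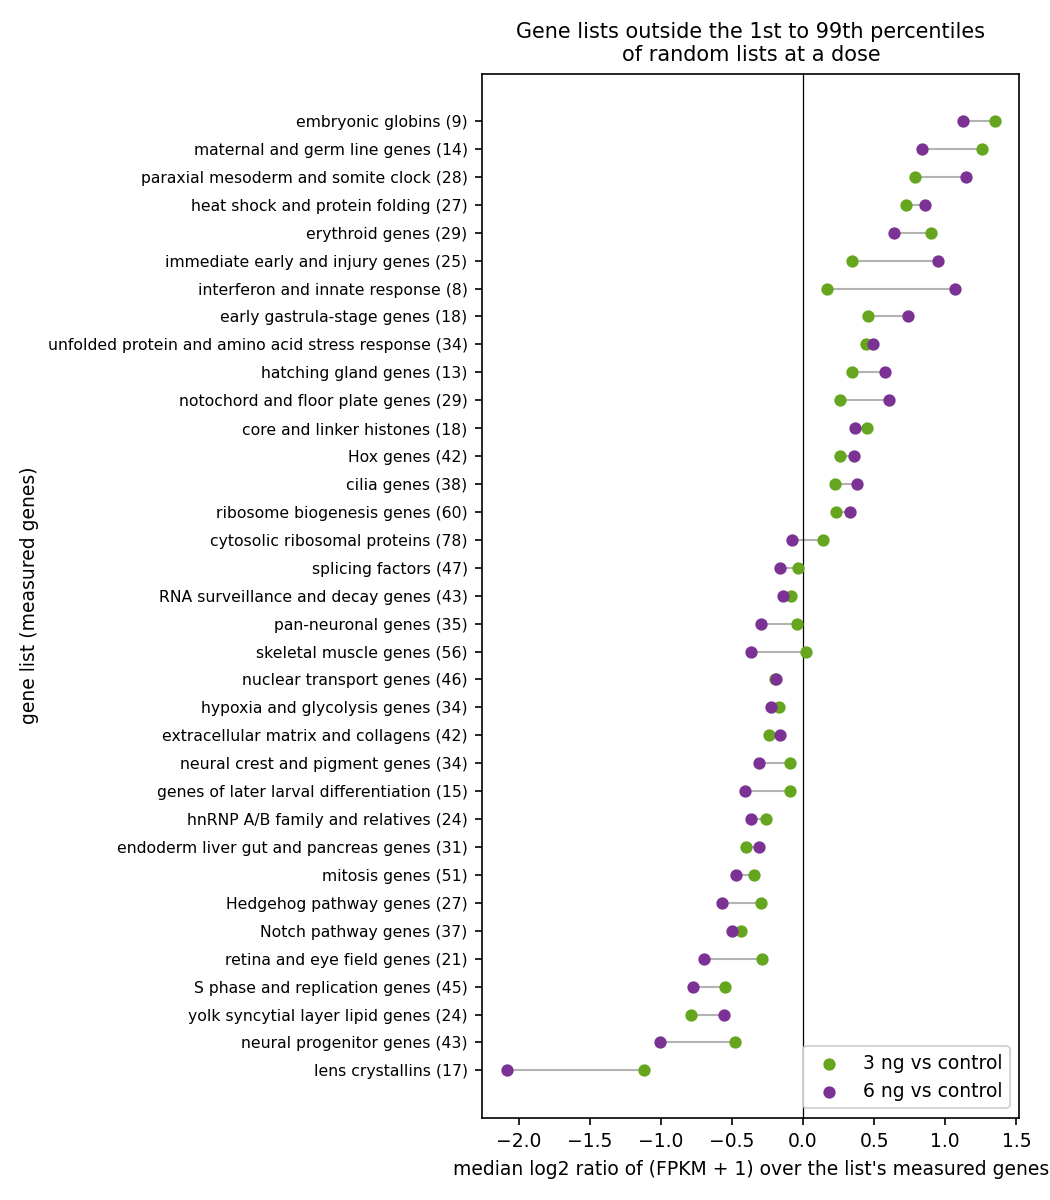
Median log2 ratio of FPKM + 1 to the control (horizontal axis) for 35 gene lists (vertical axis, number of measured genes in brackets) whose median lay outside the 1st to 99th percentiles of random lists at a dose. Green points are 3 ng, purple points 6 ng, and the lens crystallins lie lowest at -1.12 and -2.08 while embryonic globins lie at 1.35 and 1.13.

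The libraries given 6 ng and 3 ng of the same morpholino were compared without using the control. At 6 ng, injury and hatching gland genes were higher and lens and neural progenitor genes were lower than at 3 ng. mmp9 was 6.51-fold higher (5.40 to 7.89) and cxcl18b 3.85-fold higher (3.14 to 4.73), and the hatching enzyme genes he1.1 and he1.2 were 4.78-fold (4.495 to 5.08) and 3.86-fold higher (3.49 to 4.28). On the lower side, olig2 stood at 0.163-fold its 3 ng level (0.137 to 0.192), the midbrain gene en2b at 0.101-fold (0.0576 to 0.165), gch2 at 0.238-fold (0.217 to 0.261), crygn2 at 0.198-fold (0.125 to 0.303) and the metallothionein gene mtbl at 0.241-fold (0.144 to 0.386). A gene whose symbol is given as PTS, for an enzyme of pteridine synthesis, stood at 0.299-fold (0.259 to 0.344). In this comparison immediate early and injury genes had a median of 0.48, hatching gland genes 0.23, epidermis and periderm genes 0.28, lens crystallins -1.12 and neural progenitor genes -0.58. The 8 measured interferon and innate response genes, a set in which the filter favours higher members, had a median of 0.79. Of these, 4 were at least 2-fold higher and 0 lower. In all 183 genes were at least 2-fold higher and 163 at least 2-fold lower at 6 ng than at 3 ng. With a pseudocount of 0.1 FPKM the numbers were 426 and 365, with 5 FPKM they were 33 and 20, and among genes with a mean of 5 FPKM or more they were 62 and 75. After rescaling to equal sums they were 309 and 240.

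The last question was whether the 2 doses differed from the control in the same genes. Genes at least 2-fold from the control in the same direction at both doses numbered 483 higher and 254 lower, and 2 genes were past 2-fold in opposite directions (si:dkey-269i1.3 and si:dkeyp-79f12.7, named after their values were seen). Among those ranked highest were isg15, serpinh1b, rps27l, phlda3, the noncoding RNA gene rn7sk, casp8, mdm2, the Wnt agonist gene rspo1, the spliceosomal RNA U2, hsp90aa1.2 and lnx1. Those ranked lowest were hnrnpul1l, plp1a, prtgb, fabp7a, cyp1a, rbp4, lrrn1, apoa4b.2, ndst3, apoa4b.1, the gene given as GPM6B, and crybb1l2. rspo1 rested on 2 fragments in the control, with folds of 91.6 (25.1 to 761) at 3 ng and 111 (30.3 to 921) at 6 ng, and U2, listed at 0 in the control, was at least 5.75-fold higher at 3 ng and at least 10.04-fold higher at 6 ng, taking 3 fragments as the floor. These bounds leave out the counting error of U2 in the morphant libraries, and the lower limits of its exact intervals are 4.28 and 7.64. Of the genes past 2-fold at 3 ng, 80.0% of the higher and 70.4% of the lower ones were also past it at 6 ng. With a pseudocount of 0.1 FPKM the numbers higher and lower at both doses were 866 and 486, with 5 FPKM 109 and 53, among genes with a mean of 5 FPKM or more 247 and 127, and after rescaling to equal sums 619 and 454.

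Across the 16429 genes, which are not independent replicates, the log2 differences at the 2 doses had a Pearson r of 0.83 and a Spearman rho of 0.82. Both doses share the control library, and simulated unchanged libraries sharing a control gave r of 0.52 with counting error alone and 0.50 with an added coefficient of variation of 0.2. Those simulations gave 5.2 and 18 genes higher at both doses and 2.15 and 8.45 lower, and independent lists of the observed sizes would share 37.9 higher and 16.4 lower genes. The covariance was 0.3001, against 0.0729 in the simulation with added spread, a difference of 0.227. The added spread was assumed and not measured, and with 1 control library the controls could not be split. Part or all of the excess may thus come from the shared control. These values do not tell a difference common to both morphant libraries from an unusual control pool.

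**Figure D3:**
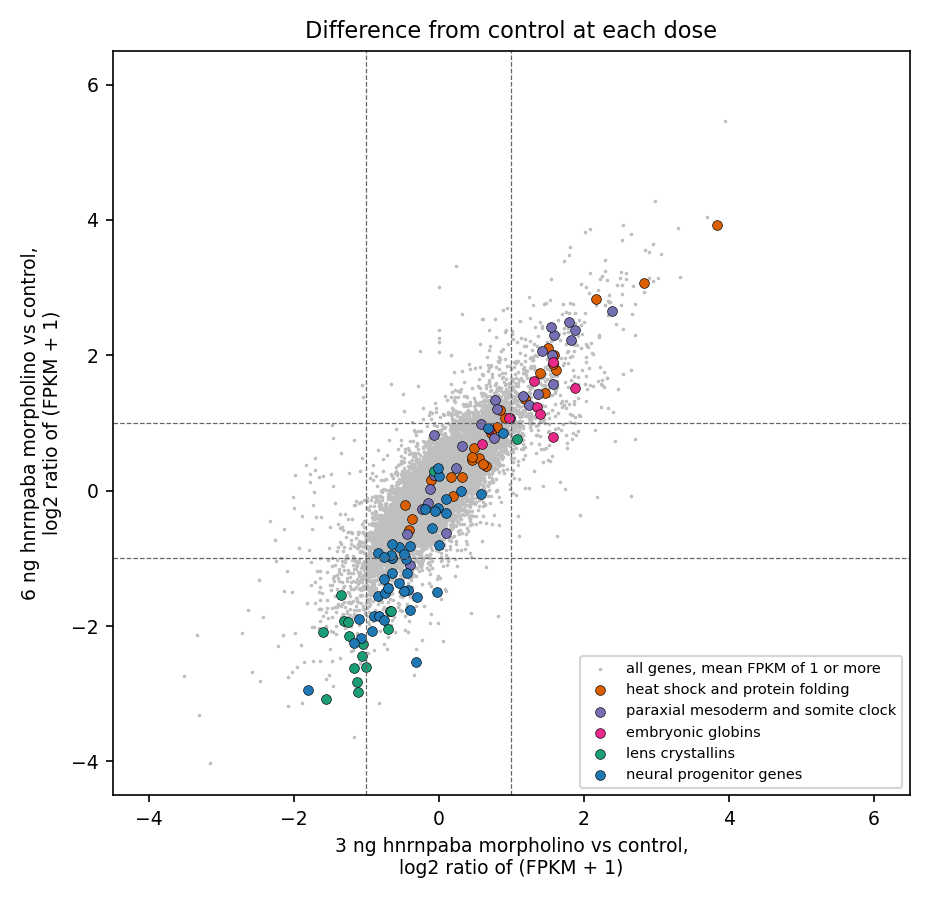
Log2 ratio of FPKM + 1 to the control at 3 ng (horizontal axis) and at 6 ng (vertical axis) for 16429 genes (grey points) and the measured members of 5 gene lists (coloured points), with dashed lines at the 2-fold limits. Heat shock and paraxial mesoderm genes lie toward the upper right and lens crystallins and neural progenitor genes toward the lower left, and r across all genes is 0.83.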

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

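The hatching enzyme genes he1.1 and he1.2, the hatching gland protease gene ctslb (the copy on chromosome 12 at 16617138 to 16619757), the glucose transporter gene slc2a1a and the fibronectin gene fn1b were singled out because they lay below the control at 3 ng and above it at 6 ng. With 1 library per group the difference between the doses was not tested. he1.1 stood at 197, 70.8 and 338 FPKM in the control, 3 ng and 6 ng libraries, a log2 difference of 2.24 between the doses. he1.2 stood at 105, 29.7 and 115 FPKM, a log2 difference of 1.91 between the doses. Its 6 ng value was close to the control, with a fold of 1.09 (1.02 to 1.18). This copy of ctslb stood at 52.1, 15.14 and 73.1 FPKM (2.199), and slc2a1a at 24.6, 8.14 and 29.5 FPKM (1.74). fn1b stood at 10.3, 9.52 and 22.6 FPKM (1.16), so that its 3 ng value was close to the control. The other copy of ctslb, on the same chromosome at 16691584 to 16694092, stood at 17.8, 2.75 and 12.8 FPKM, below the control at both doses. The neighbouring hatching enzyme gene he1.3 did not share the pattern, with 16.9, 36.9 and 81.5 FPKM. The he1 genes are tandem copies, so the division of reads between them is uncertain.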

How the results depend on the processing

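With 1 library per group no replicate could be left out. No paired analysis was possible because each group has 1 library. Counts below are given as higher and lower, for 3 ng against control, 6 ng against control, 6 ng against 3 ng and both doses. A pseudocount of 0.1 FPKM gave 1004 and 750, 1615 and 1171, 426 and 365, and 866 and 486, and one of 5 FPKM gave 137 and 79, 313 and 215, 33 and 20, and 109 and 53. A mean of 5 FPKM or more, which leaves fewer genes, gave 278 and 171, 540 and 391, 62 and 75, and 247 and 127. A limit of 1.5-fold gave 1904 and 1559, 2961 and 2011, 849 and 622, and 1590 and 1123. Rescaling to equal sums gave 693 lower genes at 3 ng, 309 higher between doses and 454 lower at both doses, and its pseudocount of 1 is smaller beside the larger values. The correlation between doses was 0.82 with a pseudocount of 0.1 FPKM, 0.85 with 5 FPKM, 0.80 without a filter and 0.87 with a mean of 5 FPKM or more, against 0.83 as reported. Other counts stayed within 1.5 times the reported ones under these settings, the median ratio and the removal of the length trend (chosen after seeing the data).

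hnrnpaba at 3 ng had a log2 difference of -0.028 after rescaling to equal sums and -0.011 with the length trend removed, and at 6 ng it had -0.41, -0.47 by the median ratio and -0.51 with the trend removed. hnrnpabb had -0.072 at 3 ng and -0.22 at 6 ng after rescaling to equal sums, and -0.27 at 6 ng by the median ratio. Among lists that stood apart, the histone list was the 1 that reversed, from 0.45 to -0.13 at 3 ng with a mean of 5 FPKM or more, which left 12 of 18 members. Of 736 list medians under the alternatives, 705 stayed on their side of the percentile limits, 23 came inside them and 7 went past them. Of 275 named values past 2-fold, 275 stayed past it with a pseudocount of 0.1 FPKM, 161 with 5 FPKM, 273 after rescaling to equal sums, 269 by the median ratio and 261 with the length trend removed. Apart from the filter and the pseudocounts, the cause of these shifts was not tested. Depth limits genes with few fragments, such as hist1h4l at 3 ng, whose fold of 5.75 has an interval of 0.739 to 259.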

Other observations

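The tests of explanations below were chosen after the results were seen. Hox genes followed their place in the clusters. The 20 measured genes of paralog groups 9 to 13, which are expressed toward the tail, had medians of 0.79 at 3 ng and 0.80 at 6 ng, with 19 of them above 0 at each dose. The 22 genes of groups 1 to 8 had medians of -0.05 and -0.25. hoxb13a stood at 3.69, 13.3 and 14.3 FPKM in the control, 3 ng and 6 ng libraries, hoxd12a at 5.47, 18.7 and 16.5 FPKM and hoxc10a at 4.08, 12.09 and 10.7 FPKM. The whole Hox list had medians of 0.26 and 0.36. Cilia genes had medians of 0.23 and 0.38, with the regulators foxj1a (4.51, 8.29 and 10.4 FPKM) and foxj1b (1.45, 4.28 and 4.01 FPKM) higher and rfx3 lower (6.95, 2.84 and 2.79 FPKM).

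Among lists of general cell functions, ribosome biogenesis genes had medians of 0.23 at 3 ng and 0.33 at 6 ng, led by imp3 (24.6, 45.8 and 59.7 FPKM). Splicing factors had medians of -0.04 and -0.16, RNA surveillance and decay genes -0.09 and -0.14, and nuclear transport genes -0.20 and -0.19, with 0 of 47, 0 of 43 and 0 of 46 members past 2-fold at 6 ng. Within the splicing list srsf1b (14.3, 28.8 and 28.6 FPKM) and srsf5b (89.3, 47.4 and 49.4 FPKM) lay on opposite sides of the control. Cytosolic ribosomal protein genes had medians of 0.14 and -0.08, and core and linker histones 0.45 and 0.37, which turned to -0.13 and -0.20 among genes with a mean of 5 FPKM or more. Hypoxia and glycolysis genes had medians of -0.17 and -0.23, with pfkma at 3.24, 1.67 and 0.705 FPKM, and extracellular matrix genes had -0.24 and -0.16, with emilin3a higher (11.5, 41.9 and 62.5 FPKM) and col6a1 lower (11.98, 5.48 and 4.02 FPKM). Genes of later larval differentiation had medians of -0.09 and -0.41. Each of these lists and those of the Hox and cilia genes stood apart from random lists at a dose or more.

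The other lists did not stand apart at either dose. Their medians at 3 ng and 6 ng were -0.05 and -0.19 for endothelial genes, -0.10 and -0.08 for Wnt pathway genes, -0.09 and -0.07 for cardiac genes, 0.02 and -0.03 for otic and lateral line genes, and 0.03 and 0.04 for housekeeping reference genes. They were 0.04 and 0.04 for cartilage and arch genes, 0.25 and 0.04 for mitochondrially encoded genes, 0.23 and 0.13 for nuclear oxidative phosphorylation genes, 0.15 and 0.17 for TGF-beta and BMP pathway genes, and -0.06 and 0.18 for FGF and retinoic acid pathway genes. They were 0.07 and 0.18 for myeloid genes, 0.19 and 0.18 for oxidative stress genes, 0.07 and 0.21 for epidermis genes, 0.21 and 0.25 for the proteasome, 0.01 and 0.28 for pronephros and ionocyte genes, 0.29 and 0.40 for blood stem cell genes, and 0.10 and 0.43 for apoptosis genes. Some of those near 0 changed sign with the scaling, such as that of the housekeeping genes at 3 ng, which was -0.055 after rescaling to equal sums. Single members still differed, such as myl7 of the heart (11.02, 5.44 and 4.25 FPKM), krt8 of the epidermis (350, 566 and 1057 FPKM), dkk1b of the Wnt pathway (4.95, 18.8 and 22.1 FPKM) and b2m, listed as a reference gene (1.87, 5.86 and 15.8 FPKM).

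Short genes were higher than long ones in the morphant libraries (medians at 3 ng of 0.17 in the 3288 shortest and -0.12 in the 3285 longest genes). The libraries hold 1 targeting reagent and no rescue, so an effect of this morpholino on RNAs other than hnrnpaba was not separated from the loss of hnrnpaba for any difference reported.

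Higher genes of early mesoderm with lower lens and neural progenitor genes may reflect younger embryos or another makeup of the pools. Uniformly younger embryos would have less embryonic globin, yet the globin median at 6 ng was 1.13, which argues against age as the whole cause. The globin and erythroid (0.64) lists cover 1 blood lineage. Among measured members, later larval differentiation genes (median -0.41 at 6 ng) and maternal and germ line genes (0.84) differed as younger embryos would. At 3 ng the later larval median of -0.09 lay inside the percentile limits, and the maternal and germ line median was 1.26. The filter favours higher members of the maternal and germ line list, and 15 of 38 later larval genes passed it. Age as a part of the cause thus stays open. Gene length is argued against, as the neural progenitor median at 6 ng was -1.15 with the length trend removed. A larger share of posterior tissue is a candidate explanation, since the log2 difference of 42 Hox genes followed their paralog group with a Spearman rho of 0.81 at 6 ng and 0.83 at 3 ng across genes, which are not independent replicates. The Hox trend may be part of the same pattern, and it was not tested against the other explanations. It therefore does not set posterior tissue above them. A slower development of head structures alone was not tested.

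Several small noncoding RNAs were higher in both morphant libraries. Fragments of 7SK RNA, a regulator of transcription elongation, were 9.86-fold higher (6.01 to 17.3) at 3 ng and 24.4-fold higher (15.06 to 42.4) at 6 ng. U1, U2, U4 and U5 RNA summed were 6.19-fold (3.60 to 11.4) and 10.3-fold higher (6.02 to 18.8), from 15 fragments in the control. 5.8S rRNA was 5.37-fold (3.73 to 7.95) and 12.25-fold higher (8.62 to 17.9), from 34 fragments in the control. More RNA of every kind without a poly(A) tail would raise 5S rRNA too, but its summed fold at 6 ng was 0.928 (0.818 to 1.05). snoRNA was 1.48-fold higher (1.32 to 1.66). microRNA precursors were not higher at 6 ng, with a fold of 0.845 (0.658 to 1.08). They had 149, 173 and 117 fragments in the control, 3 ng and 6 ng libraries, over 30 features. The 5S sum held 537, 599 and 463 fragments in the control, 3 ng and 6 ng libraries, spread over 288 features. With so few fragments per feature, it is not known whether the sum follows 5S rRNA itself, so it does not decide this explanation. Carryover set by the size of the RNA alone would give RNAs of like length like folds. At 6 ng 7SL (298 bases) was 2.395-fold higher (1.55 to 3.79), below the interval of 7SK (322 bases). Their intervals parted at 3 ng as well. This pair argues against size alone, but each RNA is 1 feature and the intervals cover counting error only. U5 RNA (median 115.5 bases) had 0, 21 and 32 fragments in the control, 3 ng and 6 ng libraries while 5S rRNA (median 117 bases) was not higher. That pair shares the doubt about the 5S sum. Other differences in how the libraries were built were not tested, and no test here bears on a biological cause.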
